A study of Homo sapiens with 4 samples.

How the data were processed

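RNA was sequenced from 4 cultures of TOV21G cells, 1 each for the control, As2O3 at 1 µM, GSK458 at 0.1 µM and both drugs. Groups and doses were taken from the sample labels, as was the time of 48 h for the 3 treated cultures, and the time of the control is not given in the sources used here. Per the labels' protocols, RNA was purified on columns and libraries were made with a stranded kit for poly(A) mRNA. The deposited table gives FPKM values, fragments per kilobase of transcript and 1000000 mapped fragments, for 26255 gene symbols, which the authors made from their reads before deposit. The submitters' processing notes name the genome build hg19, TopHat2 2.1.1, Bowtie2 2.2.8, SAMtools 0.1.18 and Cuffdiff 2.2.1, without saying which tool made which step. The gene annotation, the strand setting of the quantification and the treatment of reads that map to several places are not given in the sources used here. Values of genes that share sequence with paralogs or pseudogenes, that overlap or that are readthroughs are therefore uncertain. This covers tubulins, metallothioneins, histones, ribosomal proteins and RNF5 besides the genes marked in the text, where not every such gene is marked.

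No symbol was listed more than once, and 8375 genes were at 0 in all libraries. FPKM sums were 543975 for the control, 577409 for As2O3, 588892 for GSK458 and 566797 for both drugs, and the 10 most abundant genes took 9.51% to 11.5% of the sum. FPKM values keep no read counts, so the absolute depth is unknown and no counting interval was computed. In genes below 0.5 FPKM in the control, the ratio of the value in another library to the control value was often the same number, taken as the ratio of what 1 read is worth. This held for 350 of 617 such genes with As2O3, 354 of 615 with GSK458 and 362 of 614 with both, counting ratios near 1 that were equal after rounding to 3 decimals, and gave the relative depths. An exact 0 can be a failed estimate, so such genes are described as listed at 0.

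Values were used as deposited. Genes with a mean of at least 1 FPKM over the 4 libraries (12260 genes) entered all comparisons, on the log2 scale after adding a pseudocount of 1 FPKM. Genes at least 2-fold apart were counted per direction. With 1 library per group no test was run. Each drug's difference was computed without and with the other drug, from library pairs that share no library, and both were compared by Pearson's r across genes and by the number of genes at least 2-fold apart the same way, beside the number for independent lists. The single drugs share the control library, so their correlation was set beside that of 100 simulated sets of unchanged libraries with equal noise in each. The departure from additivity was the combination minus As2O3 minus GSK458 plus the control.

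The text names genes by a rule fixed before the data were examined. It took, among genes with at least 5 FPKM in 1 library, the 10 genes higher and the 10 lower in both pairs of each drug by the smaller of the differences, the 10 highest and lowest in the combination, the 10 largest departures each way, up to 4 members each way of a list that were at least 2-fold apart (where none was, the 2 largest), and 10 fixed genes. Among these picks were many small RNA genes, namely 3 and 3 of 10 for As2O3 higher and lower, 3 and 4 for GSK458, 6 and 9 for the combination and 10 and 9 for departures above and below additivity. The rule was applied again without small nucleolar, Cajal body, micro, spliceosomal, vault, Y and 7S RNA symbols, a choice made after the data were seen, and those genes are named. Some genes that the rule picks are not reported here.

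The 32 gene lists were fixed before the data were examined. They cover NRF2 targets, metallothioneins, heat shock, the ATF4 amino acid response, ER chaperones, p53 targets, S phase, mitosis, homologous recombination and DNA repair, FOXO targets, cholesterol synthesis, fatty acid synthesis, glycolysis and hypoxia, lysosome and autophagy, ribosome biogenesis, ribosomal proteins, aminoacyl-tRNA synthetases, oxidative phosphorylation, the interferon response, NF-kB cytokines, ERK output, receptor tyrosine kinases, PI3K and mTOR components, the BCL2 family and death receptors, extracellular matrix, clear cell carcinoma markers and histones. The last 5 are mitochondrial transcripts, immediate early genes and markers of fibroblasts, immune and endothelial cells. Some genes stand in more than 1 list. For lists with at least 5 measured genes, 28 in all, the median was set against 10000 random lists of the same size matched on mean expression in 20 bins. A list stood apart below percentile 2.5 or above 97.5, which describes these libraries and is not a test of the drugs.

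Alternatives planned before the data were examined were pseudocounts of 0.1 and 5 FPKM, no filter, a mean of at least 5 FPKM, libraries rescaled to a sum of 1000000, median-of-ratios and upper-quartile scaling, a threshold of 1.5-fold, Spearman's rho and the mean over a list. Leaving out small RNA genes or genes listed at 0 in a library was added after the data were seen. The scripts were tested on simulated libraries with 12260 genes and noise of 0.2 log2 SD, which was set, not estimated, and equal for all genes. Changes were planted, and lists drawn, only among genes with a mean of at least 5 FPKM. Recovery of lower genes and the rate of false calls at the noise of the real libraries are therefore unknown. For As2O3 against the control, 94.0% of genes changed by 1.5 log2 units and all of those changed by 2 or 3 were recovered at 2-fold, with 0.017% of unchanged genes. For the departure from additivity, 0.538% of genes passed 2-fold with no departure. Of 100 unshifted lists 1 stood apart, and a list shifted by 0.5 reached percentile 100. GC content and length came from the longest GENCODE transcript of each symbol, and random lists were matched on both in 25 bins. No coordinates are given, since the reference used here is of another build. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.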

Results

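Gene expression was measured by sequencing poly(A)-selected RNA from TOV21G cells, a human line derived from an ovarian clear cell carcinoma. The cells were left without drug or treated for 48 h. As2O3 is arsenic trioxide, a thiol-reactive drug used against acute promyelocytic leukaemia, and was given at 1 µM. GSK458 is an inhibitor of both PI3K and mTOR, the kinases at the centre of a growth pathway, and was given at 0.1 µM. The last culture received both drugs. The series title names a synergy of the 2 drugs, so each drug was compared with the control, and the combination was compared with the control, with each drug alone and with the sum of the single-drug effects.

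There was 1 library in each of the 4 groups and no replicate, so no difference below has a replicate error, a test or a p-value, and each value describes these libraries. The deposited FPKM values covered 26255 gene symbols, of which 16191 were above 0 in the control, 16157 with As2O3, 16409 with GSK458 and 16269 with both drugs. The absolute depth is unknown. The steps between low FPKM values put the depth of the As2O3 library at 96.3% of the control's, that of the GSK458 library at 109% and that of the combination library at 85.8%. Differences are given on the log2(FPKM + 1) scale for the 12260 genes with a mean of at least 1 FPKM, and this scale understates differences of low genes. A list of genes is said to stand apart where its median lies outside the central 95% of 10000 random lists matched on expression. Of 28 lists of unrelated genes, 1.4 would do so by chance in each comparison. Genes that are regulated together can move as a list between cultures, so more may stand apart without a drug effect.

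The comparison of As2O3 with the control asked what arsenic does to these cells. The genes of the antioxidant response driven by the transcription factor NRF2 were higher as a group. HMOX1, the haem-degrading enzyme haem oxygenase, stood at 30.3 FPKM in the control and 1375 FPKM with As2O3, a log2 difference of 5.46. All 24 measured NRF2 targets were higher, 17 of them at least 2-fold, with a median of 1.34 at percentile 100. They included TXNRD1, a thioredoxin reductase (60.6 against 470 FPKM), SLC7A11, the cystine transporter (0.81 against 11.2 FPKM), GCLM, a subunit of the enzyme that limits glutathione synthesis (8.56 against 41.4 FPKM), and SRXN1 (14.0 against 61.8 FPKM). NQO1, a quinone reductase, stood at 727 and 1807 FPKM, and the ferritin heavy chain FTH1, which has many processed pseudogenes and is therefore uncertain, at 4300 and 15008 FPKM.

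Several stress-response lists were also higher with As2O3, while ER chaperones were not (median −0.14, percentile 3.23, 4 of 18 genes higher). In the ATF4 amino acid response, 25 of 27 genes were higher and 15 at least 2-fold (median 1.18, percentile 100), among them ATF3, DDIT3 and CHAC1 with log2 differences of 2.94, 2.84 and 2.26. DDIT3, a transcription factor of the integrated stress response, stood at 9.26 FPKM in the control and 72.7 FPKM with As2O3. The p53 target list had a median of 0.45 (percentile 100), with 19 of 24 genes higher but only 3 at least 2-fold. These were the secreted stress marker GDF15 (99.9 against 836 FPKM), the cell cycle inhibitor CDKN1A (79.7 against 244 FPKM) and PLK3. Of the NF-kB cytokine list 19 of 20 genes were higher (median 0.74, percentile 100), including SOD2, NFKB2, LIF and CXCL5. CCL2 was the exception, at 4.88 FPKM in the control and 0.82 FPKM with As2O3. The ERK output list had 21 of 24 genes higher (median 0.67, percentile 100), led by the phosphatase DUSP5 (10.8 against 174 FPKM), FOS and FOSL1. The list of immediate early genes, which handling of a culture can also induce, moved with these lists. All 15 of its genes were higher with As2O3, with a median of 1.23 (percentile 100) and log2 differences of 2.72 for NR4A1 and 2.31 for FOS.

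Other lists stood apart with As2O3 as well. The metal-binding metallothioneins were higher in 6 of 6 genes (median 0.43, percentile 98.9), with MT2A at 212 and 816 FPKM. Medians were 0.38 for mitotic genes (30 of 32 higher, percentile 100), 0.28 for aminoacyl-tRNA synthetases (percentile 99.8) and 0.26 for genes of the BCL2 family and death receptors (percentile 99.9). In that last list the pro-apoptotic PMAIP1 had a log2 difference of 2.41. Medians were 0.25 for glycolysis and hypoxia genes (percentile 99.9), where NDRG1 and SLC2A3 had log2 differences of 1.90 and 1.58, and 0.28 for extracellular matrix genes (percentile 99.9), with none at least 2-fold and the call lost for the mean over the list. The heat shock list stood at percentile 99.7, with CRYAB alone at least 2-fold higher at 1.64. FOXO targets had a median of 0.18 (percentile 98.0), led by GADD45A at 2.51, and did not stand apart with a pseudocount of 5 FPKM or a mean of at least 5 FPKM. The S phase list was lower (median −0.21, percentile 0.26, 9 of 31 higher). Replication-dependent histones were lower in 6 of 6 measured genes (median −1.17, percentile 0), and histone values rest on messages that mostly lack a poly(A) tail.

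Each drug's effect could be read again from the libraries that also held the other drug, which share no library with the first pair. Without the other drug 254 genes were at least 2-fold higher and 173 lower with As2O3, while in the presence of GSK458 only 79 were higher and 39 lower. Of these, 31 genes were higher in both pairs against 1.64 for independent lists, and 10 were lower in both against 0.55. Another 9 went opposite ways by at least 2-fold, 3 of them higher and 6 lower without GSK458. Among genes that are not small RNA genes, a choice made after the data were seen, 1 did so. The correlation of the 2 differences across genes, which are not independent replicates, was 0.23 (Spearman's rho 0.26). It was 0.14 with a pseudocount of 0.1 FPKM, and 0.34 without small RNA genes, a choice made after the data were seen. Besides HMOX1, TXNRD1, SLC7A11, GCLM, SRXN1, NQO1 and DUSP5, the genes highest in both pairs were AKR1C1, whose near-identical family members make its value uncertain, GCLC (7.77 against 21.2 FPKM without GSK458 and 8.68 against 23.7 FPKM with it) and TFPI2, a protease inhibitor and clear cell carcinoma marker. TFPI2 stood at 32.0 FPKM in the control, 664 with As2O3, 109 with GSK458 and 301 with both. The 10 genes lowest in both pairs were CCL2, VEPH1, CTDSP1, EDN1, DEFB1, ENHO, NCCRP1, GLT8D2, BLOC1S5-TXNDC5 and SLC34A2. CTDSP1, a phosphatase, stood at 59.7 FPKM in the control, 13.1 with As2O3, 78.1 with GSK458 and 33.5 with both. SLC34A2, a phosphate transporter, stood at 135, 39.2, 85.8 and 45.05 FPKM in the same order. BLOC1S5-TXNDC5 is a readthrough of neighbouring genes whose reads it shares, so its value is uncertain. With each library rescaled to a sum of 1000000, the split of the 2-fold genes against control was 246 higher and 292 lower.

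**Figure D1:**
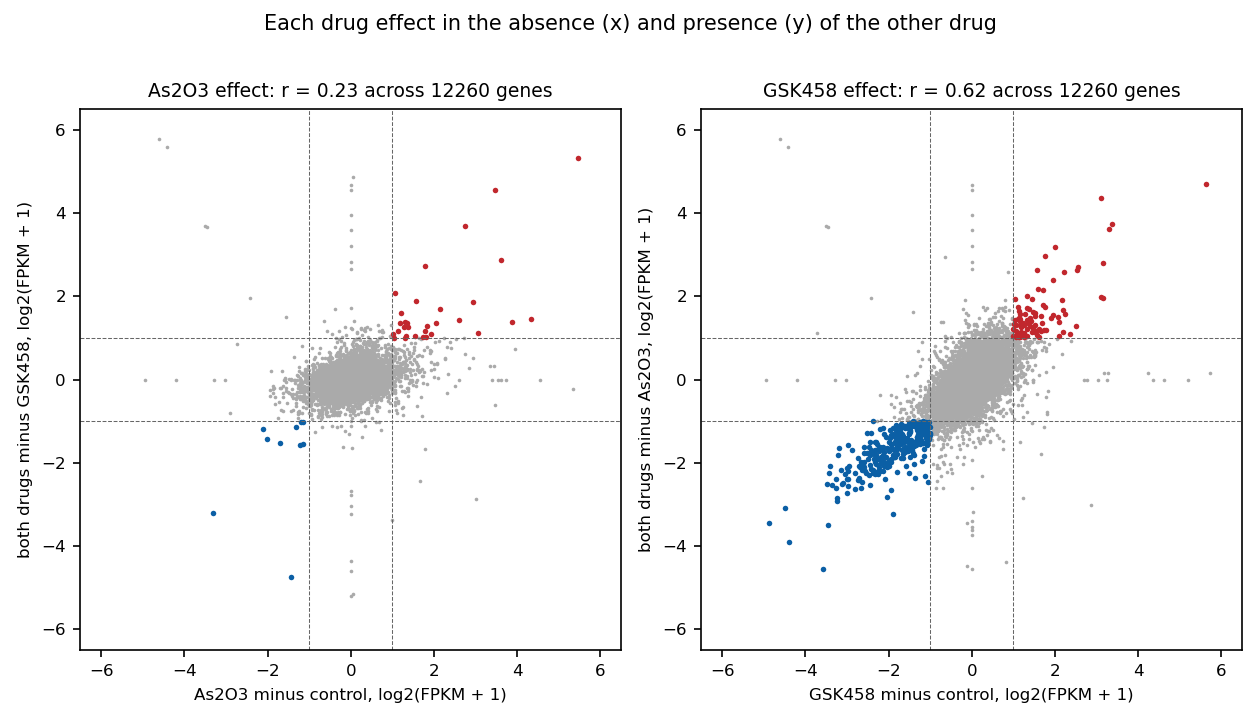
Each point is 1 of 12260 genes, with the log2(FPKM + 1) difference made by a drug without the other drug on the x axis and with it on the y axis, for As2O3 (left) and GSK458 (right). Dashed lines mark 2-fold, and red and blue points are at least 2-fold higher or lower in both pairs, 31 and 10 genes for As2O3 and 93 and 306 for GSK458. Points lying exactly on 0 of an axis have equal values in that pair of libraries.

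The comparison of GSK458 with the control asked what inhibition of PI3K and mTOR does. Genes of DNA replication and mitosis were lower. All 32 mitotic genes were at least 2-fold lower than in the control (median −2.65, percentile 0), and 26 of 31 S phase genes were (median −1.89, percentile 0). RRM2, a subunit of the enzyme that makes deoxyribonucleotides, stood at 52.1 FPKM in the control and 1.36 FPKM with GSK458. CDC20, an activator of the anaphase-promoting complex, stood at 80.1 and 6.29 FPKM, the kinase AURKB at 41.9 and 3.56 FPKM, the ubiquitin-conjugating enzyme UBE2C at 90.2 and 8.72 FPKM, and cyclin A2 (CCNA2) at 27.5 and 2.62 FPKM. KIF2C, BUB1, CDCA8, FAM64A and PBK completed the 10 genes lowest in both pairs, all with log2 differences between −2.66 and −3.37 against the control. Of the genes of homologous recombination and DNA repair, 15 of 27 were at least 2-fold lower (median −1.12, percentile 0), among them RAD54L, RAD51AP1 and EXO1.

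Metabolic lists were lower with GSK458 as well. Of 24 genes of cholesterol synthesis, 1 was higher (median −0.59, percentile 0), and ACAT2 and INSIG1 were among those at least 2-fold lower. In the fatty acid synthesis list SCD, FADS2, SREBF1 and ELOVL6 had log2 differences of −2.08, −1.54, −1.42 and −1.10. The median of that list (−0.29, percentile 2.46) was at the edge, and it did not stand apart in 7 alternative settings. Medians were −0.62 for glycolysis and hypoxia (10 of 30 genes at least 2-fold lower, percentile 0, with PGAM1, HK2, TPI1 and PGK1 lowest), −0.62 for ER chaperones (CALR, SDF2L1, PDIA4 and CRELD2 lowest, percentile 0) and −0.42 for nuclear genes of oxidative phosphorylation (35 of 38 genes lower, none 2-fold, percentile 0). The ATF4 list had a median of −0.33 (percentile 0.07), with DDIT4, PHGDH, SESN2 and PSAT1 at −1.93, −1.91, −1.30 and −1.19. Aminoacyl-tRNA synthetases stood at −0.32 (percentile 1.18, WARS at −1.11) and ribosome biogenesis at −0.19 (percentile 2.44), the last not apart for the mean over the list.

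Higher with GSK458 were FOXO targets, ribosomal proteins and ERK output genes. FOXO factors are held inactive by the kinase AKT downstream of PI3K, and 22 of their 26 targets were higher (median 0.49, percentile 100). PIK3IP1, IRS2 and IGF1R had log2 differences of 1.46, 1.38 and 1.28 and YPEL3 stood at 9.26 and 46.2 FPKM. IRS2, an adaptor of the insulin receptor, stood at 4.98 and 14.5 FPKM. TSC22D3, a glucocorticoid-induced gene of the same list, was lower at −1.13. All 56 genes of the cytosolic ribosomal protein list were higher by less than 2-fold (median 0.54, percentile 100), the median kept its direction under each scaling, and many of these genes have processed pseudogenes. The ERK output list had 19 of 24 genes higher (median 0.41, percentile 100). The genes highest in both GSK458 pairs were led by GPX3, a secreted glutathione peroxidase and clear cell carcinoma marker, at 2.12 FPKM in the control, 4.55 with As2O3, 155 with GSK458 and 144 with both. SHISA2, CYP27A1 (4.26 against 29.3 FPKM without As2O3), RIMKLB (18.2 against 89.1 FPKM), HSD17B2, TMEM27, FAM134B, SPON2 and LOC100505817 followed. H3F3A was listed near 0 in the control and As2O3 libraries and at 9.47 and 12.5 FPKM in the others; near-identical copies and pseudogenes make this gene uncertain.

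GSK458 differed from the control by at least 2-fold at 288 genes that were higher and 475 that were lower, and the combination differed from As2O3 alone at 280 and 524 genes. In both pairs 93 genes were higher (6.58 for independent lists) and 306 lower (20.3). Another 13 went opposite ways by at least 2-fold, and 4 did so among genes that are not small RNA genes. The correlation across genes was 0.62 (Spearman's rho 0.61), and 456 of the 475 lower genes had the same sign in the other pair. In this second pair, medians were −2.17 for mitosis (percentile 0), −1.32 for the S phase list (percentile 0), −0.97 for homologous recombination (percentile 0), −0.80 for cholesterol synthesis (percentile 0), 0.30 for FOXO targets (percentile 100) and 0.26 for ribosomal proteins (percentile 100). ERK output genes, higher with GSK458 alone, had a median of −0.21 there and did not stand apart (percentile 6.09, 7 genes at least 2-fold lower and 1 higher).

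**Figure D2:**
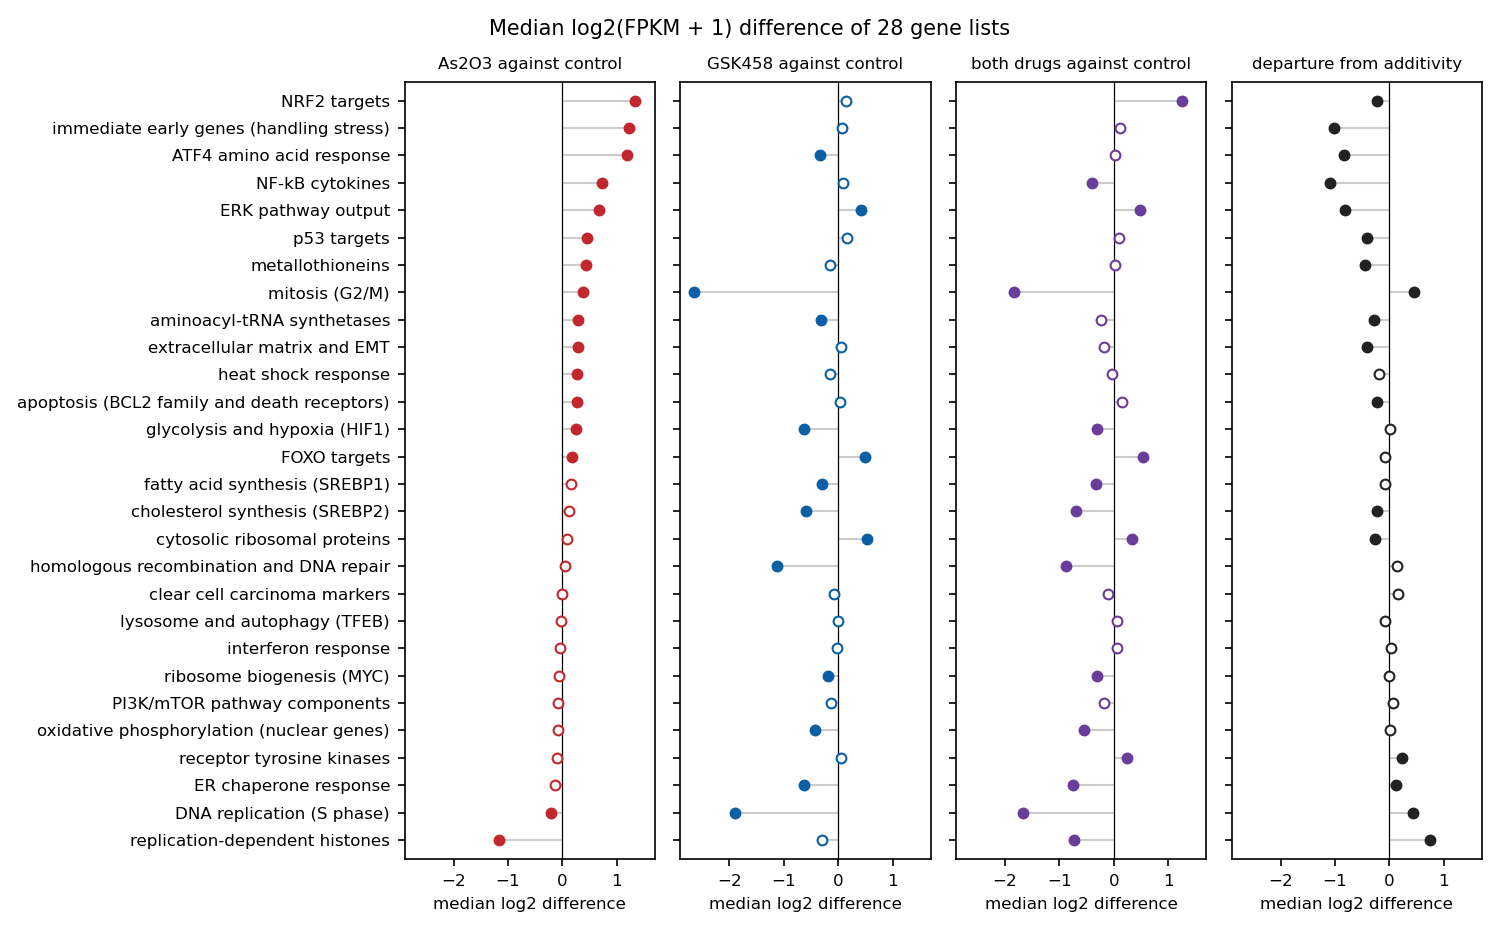
Median log2(FPKM + 1) difference on the x axis for 28 gene lists on the y axis, in As2O3, GSK458 and the combination against the control and for the departure of the combination from the sum of the single-drug differences. Filled points stand outside the central 95% of 10000 matched random lists and open points inside it; NRF2 targets lie at 1.34, 0.15 and 1.26 against the control, and mitotic genes at 0.38, −2.65 and −1.83.

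In the combination, NRF2 targets were higher than in the control in 24 of 24 genes (median 1.26, percentile 100), and HMOX1 reached 1949 FPKM. Mitotic genes were lower in 32 of 32 genes, 31 of them at least 2-fold (median −1.83, percentile 0), and S phase genes in 30 of 31 (median −1.67, percentile 0). FOXO targets were higher (median 0.53, percentile 100), as were ribosomal proteins (0.33, percentile 100) and ERK output genes (0.48, percentile 100). The ATF4 response (median 0.02, percentile 68.9), immediate early genes (0.11, percentile 83.1) and p53 targets (0.10, percentile 89.5), each higher with As2O3, did not stand apart from random lists in the combination against the control. Lower lists were homologous recombination (−0.88, percentile 0), ER chaperones (−0.74, percentile 0), cholesterol synthesis (−0.70, percentile 0), oxidative phosphorylation (−0.55, percentile 0), ribosome biogenesis (−0.31, percentile 0.08), glycolysis and hypoxia (−0.31, percentile 0.61), histones (−0.73, percentile 0.21) and fatty acid synthesis (−0.33, percentile 2.16), the last lost with a mean of at least 5 FPKM.

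In all, 399 genes were at least 2-fold higher and 528 lower in the combination than in the control. The 10 highest were HMOX1, GPX3, SNHG25, H3F3A, RIMKLB, SLC7A11, SHISA2, LOC100505817, TXNRD1 and TFPI2. SNHG25, a short host gene of a small nucleolar RNA, was listed at 0 in the control and at 39.7, 52.2 and 44.6 FPKM with As2O3, GSK458 and both, so no fold is given and the value is uncertain. RIMKLB, a glutamate ligase, stood at 18.2, 36.5, 89.1 and 224 FPKM in the control, As2O3, GSK458 and combination libraries. Among the lowest were RRM2 (52.1 against 2.41 FPKM), the antimicrobial peptide DEFB1 (89.2 against 8.02 FPKM), RCAN2 (28.1 against 1.93 FPKM), the fibrinogen chain FGB (87.1 against 12.2 FPKM), RGS2, UHRF1, LOC101929633, ASF1B and ANXA13. The NF-kB cytokine list, higher with As2O3, was lower in the combination than in the control (median −0.39, percentile 0.06), with CXCL1, CXCL2, CXCL5 and CCL2 lowest at −1.81, −1.41, −1.37 and −1.30 while SOD2 was higher at 1.93. Its median was 0.10 among genes with a mean of at least 5 FPKM, and the call was also lost for the mean over the list.

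Set against As2O3 alone, the combination was lower for the ATF4 response (median −1.01, percentile 0, 14 of 27 genes at least 2-fold, with PHGDH, ASNS, MTHFD2 and SLC7A5 lowest), immediate early genes (−0.91, percentile 0), NF-kB cytokines (−0.79, percentile 0), metallothioneins (−0.67, percentile 0.16) and p53 targets (−0.34, percentile 0.24). The NRF2 list was not apart there (−0.21, percentile 7.75).

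Set against GSK458 alone, the combination differed at few genes, 79 higher and 39 lower at least 2-fold. Of these 118 genes 36 were small RNA genes, and without them, a choice made after the data were seen, 60 were higher and 22 lower. With each library rescaled to a sum of 1000000, 121 were higher and 51 lower. NRF2 targets were higher in 23 of 24 genes (median 1.03, percentile 100). Mitotic genes were higher in 31 of 32 (median 0.82, percentile 100), 10 of them at least 2-fold, including MKI67, FOXM1, PLK1 and TOP2A with log2 differences of 1.41, 1.27, 1.26 and 1.22. S phase genes were higher in 26 of 31 (median 0.22, percentile 100), with none 2-fold apart. The medians of both lists against the control and against As2O3 remained below 0. Other lists higher than with GSK458 alone were glycolysis and hypoxia (0.26, percentile 100, with SLC2A1 and ADM at 1.16 and 1.01), metallothioneins (0.25, percentile 99.9), homologous recombination (0.23, percentile 100), the ATF4 response (0.18, percentile 100), heat shock (0.10, percentile 99.7), the lysosome list (0.05, percentile 98.9, lost for the mean over the list) and immediate early genes (0.32, percentile 100). Histones (−0.54, percentile 0), NF-kB cytokines (−0.29, percentile 0), extracellular matrix genes (−0.26, percentile 0), ribosomal proteins (−0.19, percentile 0.08) and ribosome biogenesis (−0.11, percentile 0.26) were lower.

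Some lists did not stand apart from random lists in any drug-against-control comparison. The interferon response had medians of −0.04 with As2O3, −0.03 with GSK458 and 0.07 with both, though IRF7 was higher with As2O3 at 1.41 and OAS3 lower with GSK458 at −1.16. Genes of lysosome and autophagy had medians of −0.02, −0.01 and 0.06, with GABARAPL1 higher in all 3 at 1.06, 1.32 and 1.49 and SQSTM1 at 1.55 in the combination. Components of the PI3K and mTOR pathway had medians of −0.08, −0.14 and −0.18. Within that list the regulatory subunit PIK3R3 was lower in all 3, at 23.2 FPKM in the control, 5.28 with As2O3, 5.33 with GSK458 and 3.83 with both, and EIF4EBP1 was higher with As2O3 at 1.18. PIK3CA stood at 10.2, 11.7, 12.4 and 11.8 FPKM and MTOR at 13.6, 12.2, 9.83 and 10.7 FPKM. Clear cell carcinoma markers had medians of −0.01, −0.07 and −0.11, but means of opposite sign for GSK458 (0.53) and the combination (0.76), with GPX3 and TFPI2 the highest members. Receptor tyrosine kinases stood apart from random lists against the control only in the combination (median 0.24, percentile 98.2, lost without the filter and for the mean), where IGF1R and AXL were at 1.43 and 1.17 and FGFR4 and FGFR2 at −1.42 and −1.09.

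**Figure D3:**
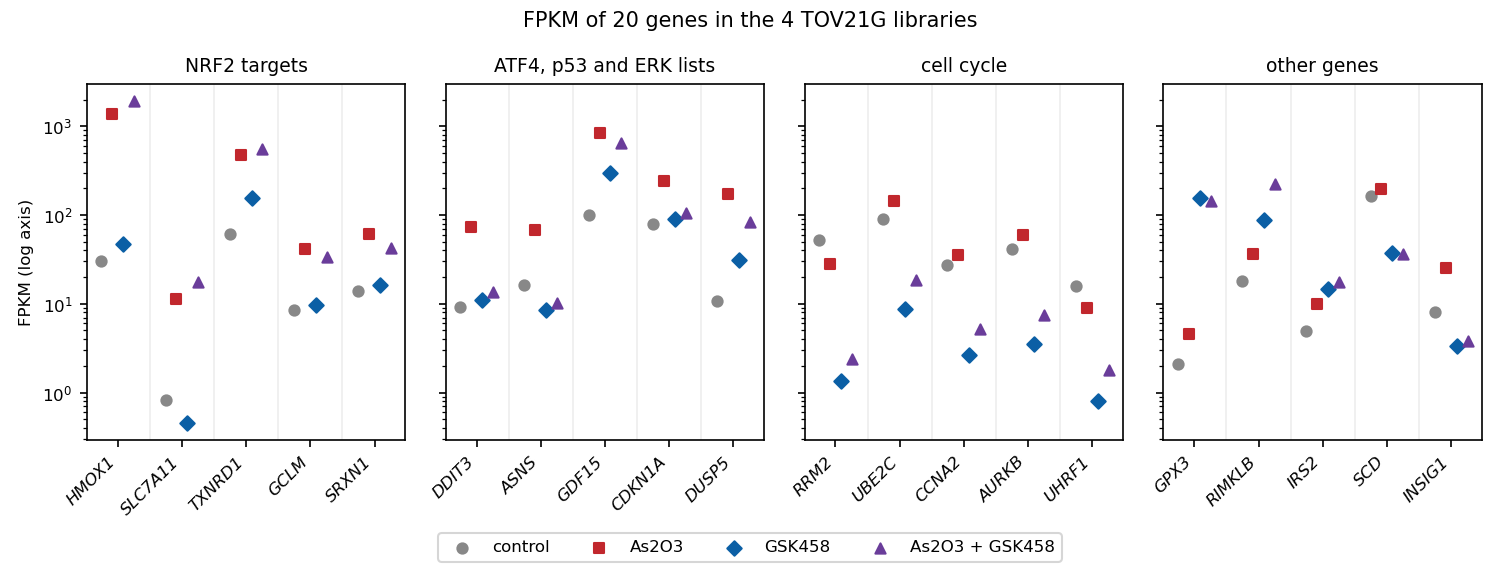
FPKM of 20 genes on a log y axis in the control, As2O3, GSK458 and combination libraries, 1 point per library and gene. HMOX1 lies at 30.3, 1375, 47.2 and 1949 FPKM in that order, DDIT3 at 9.26, 72.7, 11.1 and 13.7 FPKM, RRM2 at 52.1, 28.2, 1.36 and 2.41 FPKM, and GPX3 at 2.12, 4.55, 155 and 144 FPKM.

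The effects of the single drugs were compared with each other through the control library that both share. The correlation across genes of the As2O3 and GSK458 differences was 0.32. Unchanged groups of equal noise simulated against 1 shared control gave 0.50, a value that this design fixes whatever the noise. Drug effects can move the correlation either way, so setting 0.32 beside 0.50 does not decide whether the effects are alike. The covariance of these differences was 0.0865, against 0.0515 in the simulation, whose noise was set from the combination and GSK458 libraries. Those libraries also differ by As2O3, so that noise includes any As2O3 effect and 0.0515 is not a level without drug effects. The covariance of the As2O3 difference with the GSK458 difference taken against the As2O3 library, which a shared library biases the other way, was −0.0996. The mean of both covariances was −0.0065. The second of them also holds any departure from additivity, so their mean does not only cancel the shared-library bias. There were 55 genes at least 2-fold higher with both single drugs (5.97 for independent lists) and 43 lower with both (6.70), and part of that excess may come from the shared control. Genes at least 2-fold higher with each drug included TXNRD1, TFPI2, DUSP5, GDF15 and GADD45A. MYC stood at 45.2, 96.2, 88.4 and 57.0 FPKM and TXNIP, a thioredoxin-binding protein, at 184, 388, 347 and 237 FPKM in the control, As2O3, GSK458 and combination libraries. CCND1 ranged from 25.3 to 34.4 FPKM.

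The departure from additivity was the combination difference minus the sum of the single-drug differences on the log2 scale. It describes RNA levels only. No measurement of growth or survival was used here, so it does not show whether the drugs act in synergy on the cells, as the title names. Several of the stress lists that were higher with As2O3 were lower in the combination than the sum, while the heat shock list did not stand apart (median −0.20, percentile 9.54). The departure subtracts the As2O3 library and adds the control. Noise in either library therefore lowers the departure of lists or genes picked as higher with As2O3, and its share in these departures was not estimated. DDIT3 stood at 9.26 FPKM in the control, 72.7 with As2O3, 11.1 with GSK458 and 13.7 with both, a departure of −2.56. The ATF4 list departed by a median of −0.84 (percentile 0), with 12 of 27 genes at least 2-fold below additivity, and the combination stood at 10.2 FPKM for ASNS, the asparagine synthetase, against 67.8 with As2O3, and at 6.47 FPKM for PHGDH, an enzyme of serine synthesis, against 69.4. NF-kB cytokines departed by −1.08 (percentile 0, 14 of 20 genes at least 2-fold below, led by CCL20, CXCL5, TNF and NFKB2), ERK output genes by −0.82 (percentile 0, with DUSP5, EREG, PHLDA1 and FOS lowest) and p53 targets by −0.42 (percentile 0.01). CDKN1A stood at 79.7, 244, 90.4 and 105 FPKM and GDF15 at 99.9, 836, 300.5 and 652 FPKM in the control, As2O3, GSK458 and combination libraries. Immediate early genes departed with them, all 15 below additivity (median −1.02, percentile 0).

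Other lists below additivity were metallothioneins (−0.44, percentile 1.02, lost for the mean over the list), extracellular matrix genes (−0.41, percentile 0), aminoacyl-tRNA synthetases (−0.29, percentile 0.22), ribosomal proteins (−0.26, percentile 0.09), cholesterol synthesis (−0.24, percentile 0.60) and the BCL2 family and death receptors (−0.23, percentile 0.39). In the last of these PMAIP1 stood at 1.95, 14.6, 0.95 and 2.32 FPKM. NRF2 targets departed by −0.23 (percentile 1.14, lost for the mean over the list). Of the 24 genes 9 lay above additivity, none by 2-fold, and 2 were at least 2-fold below, TXNRD1 (−1.07) among them. HMOX1 departed by −0.12 and SLC7A11 by 0.94. Lists above additivity were histones (0.75, percentile 99.9), mitosis (0.46, percentile 100), S phase (0.44, percentile 100), receptor tyrosine kinases (0.23, percentile 98.9, lost without the filter and for the mean) and ER chaperones (0.13, percentile 98.5). Noise in a single-drug or control library likewise raises the departure of lists or genes lower with that drug, and its share was not estimated. Histones were lower with As2O3 (−1.17), and mitosis (−2.65) and S phase (−1.89) with GSK458. FOXO targets, glycolysis, oxidative phosphorylation and fatty acid synthesis did not stand apart, at −0.07, 0.01, 0.01 and −0.08.

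At least 2-fold departures were found for 163 genes above and 251 below additivity. With each library rescaled to a sum of 1000000 the split was 351 above and 215 below, as that scaling shifted the median of all genes by 0.13 for the departure and by −0.11 for GSK458 against the control. The 10 genes furthest below were SNHG25, VGF, TFPI2, GADD45A, RNF5, DDIT3, DUSP5, ATF3, EREG and MAFF. VGF, a secreted neuropeptide precursor, stood at 0.58 FPKM in the control, 23.3 with As2O3, 0.62 with GSK458 and 1.67 with both. GADD45A, a stress-induced growth arrest gene, stood at 4.78, 32.0, 12.01 and 10.6 FPKM. Those furthest above were CDC37L1-AS1, SPRY4-IT1, BASP1P1, SGK1, NEDD8-MDP1, CYS1, STS, LOC101930071, HIST2H2AC and HNRNPM. Of these, SGK1, a kinase downstream of PI3K, stood at 20.5 FPKM in the control, 5.86 with As2O3, 3.66 with GSK458 and 4.33 with both, so it was lower with each treatment. The splicing factor HNRNPM stood at 104, 34.2, 54.5 and 56.0 FPKM. SGK1 and HNRNPM were highest in the control, so noise that raised them in that library would raise their departures too. CDC37L1-AS1 was listed at 0 with As2O3 and at 5.61, 3.25 and 6.71 FPKM in the control, GSK458 and combination libraries, so its departure rests on that 0. CDC37L1-AS1 and SPRY4-IT1 overlap other genes, BASP1P1 is a pseudogene and NEDD8-MDP1 a readthrough, so their values are uncertain.

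Markers of other cell types were low in all 4 libraries. Of the fibroblast markers, COL1A1 alone had a mean of at least 1 FPKM, at 2.65, 4.24, 1.84 and 1.58 FPKM. Of the immune markers, CD8A stood at 1.18, 1.21, 1.94 and 1.79 FPKM and CD68, a lysosomal protein, at 0.78, 4.15, 1.12 and 2.63 FPKM, higher in both libraries with As2O3. No endothelial marker reached that mean, with ESAM the highest at 1.66 FPKM. None of the 15 listed transcripts of the mitochondrial genome had a value in the table, so the share of mitochondrial reads was not analysed here.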

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

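The tests of arsenic exposure, of GC content and length, of handling, of low values, of single cultures and of small RNA read numbers were chosen only after the results were seen. Some results went one way in the library pair without the other drug and the opposite way in the pair with it. Each such difference was not tested, since each pair is 1 library against 1. Genes were taken where both differences were at least 2-fold, and small RNA genes were left out. For As2O3, the S phase list had medians of −0.21 without GSK458 and 0.22 with it, a departure of 0.44. The NF-kB cytokine list had medians of 0.74 and −0.29, a departure of −1.08. The extracellular matrix list had medians of 0.28 and −0.26, with a median departure of −0.41. For GSK458, DUSP5 was at 1.46 without As2O3 and −1.05 with it (departure −2.50), GADD45A at 1.17 and −1.51 (departure −2.68) and TFPI2 at 1.74 and −1.14 (departure −2.88). NARR was listed at 0 with As2O3 and with GSK458, and at 4.36 and 2.89 FPKM in the control and the combination, so no fold is given. Its departure of 4.38 on the log2(FPKM + 1) scale counts for both drugs and rests on those zeros, and its overlap with another gene makes it uncertain.

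The stress lists of As2O3 (ATF4, NF-kB, ERK, p53 and immediate early genes, 106 genes outside the NRF2 list) had a median of 0.76 with As2O3 alone, −0.02 when As2O3 was added to GSK458, and a departure of −0.80. Noise in the As2O3 or control library that raised the first of these values would also lower the departure. GC content and gene length were not the whole cause, since the median departure minus that of random lists matched on both was −0.79 (percentile 0). A weaker arsenic exposure in the combination culture cannot be told apart from the drug effect. NRF2 targets kept 0.77 of their median difference and the pooled stress lists −0.03, a gap of 0.80 (95% bootstrap interval over genes 0.62 to 1.07, without error between cultures). The stress lists were pooled after their departures were seen, which can widen the gap. Singly, their medians in the combination against GSK458 were 0.32 for immediate early genes and 0.18 for ATF4 (percentile 100 each). They were −0.04 for p53, −0.05 for ERK and −0.29 for NF-kB (percentile 0). Metallothioneins kept 0.57 and the heat shock list 0.36, and lists with different dose responses could part in this way. A difference between single cultures, handling included, cannot be told apart either, as immediate early genes departed by −1.02 and each group has 1 library. An effect of GSK458 on these responses stays open as a hypothesis that was not tested, and NRF2 targets were themselves below additivity, at −0.23.

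Mitotic genes lay above S phase genes by 0.59 with As2O3 against the control and by 0.59 in the combination against GSK458, pairs that share no library. Against random lists matched on GC content and gene length, the smaller of both excesses was 0.588 (percentile 100 in both pairs), so these were not the whole cause. Low values with GSK458 do not enter the pair without it, and among members with at least 5 FPKM in both GSK458 libraries (10 mitotic and 17 S phase genes) the difference in that pair was 0.566 (95% bootstrap interval over genes 0.413 to 0.911). A difference between single cultures cannot be told apart from it with 1 library per group. Both lists also lay less far below the control in the combination than with GSK458 alone. Medians were −1.83 against −2.65 for mitosis and −1.67 against −1.89 for S phase. In the combination against GSK458, a smaller GSK458 effect in that culture was not tested and cannot be told apart from an effect of As2O3. A biological explanation of the gap between the lists is weighed among the other observations.

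Small RNA genes filled many of the most extreme ranks, 10 of the 10 largest departures above additivity among them. Their ratios between libraries were whole multiples within 0.02 in 53.01% of cases (44 of 83), against 3.78% (1355 of 35830) for other genes of the same FPKM range, which is consistent with values that rest on a few reads. No biological explanation was tested for them.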

How the results depend on the processing

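Leaving out small RNA genes and leaving out genes listed at 0 were chosen after the data were seen. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out and no other split of the samples could be made. Depth limits the low genes most, and the steps between low values put that of the combination library at 85.8% of the control's. Median-of-ratios scaling multiplied the libraries by only 0.987 to 1.007, so its part in the totals that follow is a weak check. Under other pseudocounts and scalings, named genes that were at least 2-fold apart stayed so in 4195 recomputed values. They fell under 2-fold in 300, of which 240 came from a pseudocount of 5 FPKM, and none turned. List medians kept their side of the central 95% in 1626 recomputed values, moved out of it in 22, moved into it in 23 and turned in 3. The NF-kB list in the combination against the control went to 0.10 with a mean of at least 5 FPKM, the cause of which was not tested, and the clear cell carcinoma markers went to 0.53 for GSK458 and 0.76 for the combination for the mean over the list, where GPX3 and TFPI2 lie far above the other members. The number of lists apart stayed between 14 and 16 for As2O3, 13 and 16 for GSK458, 14 and 17 for the combination, 18 and 21 and 13 and 15 for it against As2O3 and GSK458, and 15 and 18 for departures in every setting run. The correlation stayed between 0.53 and 0.70 for the GSK458 pairs and between 0.28 and 0.34 for the single drugs.

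Counts of genes at least 2-fold apart moved by more than 1.5 times under some settings, and a smaller pseudocount or threshold calls more genes by its construction. With a pseudocount of 0.1 FPKM they were 729 for As2O3 (427 as reported), 1277 for the combination against As2O3 (804), 270 for it against GSK458 (118) and 781 for departures (414). With a pseudocount of 5 FPKM they were 188, 345, 52 and 155 in that order, 382 for GSK458 (763) and 423 for the combination against the control (927). With a mean of at least 5 FPKM, which tests fewer genes, they were 281 for As2O3, 76 for the combination against GSK458 and 246 for departures. At 1.5-fold they were 1702 for As2O3, 2323 for GSK458, 2646 for the combination, 2587 and 457 for it against As2O3 and GSK458, and 1729 for departures. Genes apart the same way in both pairs numbered 82, 24 and 179 for As2O3 (41 as reported) at 0.1 FPKM, 5 FPKM and 1.5-fold, and 194 and 1180 for GSK458 (399) at 5 FPKM and 1.5-fold.

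The correlation between the As2O3 pairs was 0.14 with a pseudocount of 0.1 FPKM, 0.31 with one of 5 FPKM, 0.34 without small RNA genes and 0.35 without genes listed at 0 (0.23 as reported), the cause of which was not tested. The mean of the covariances that compares the single drugs was 0.0015 with a mean of at least 5 FPKM against −0.0065, and the cause was not tested.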

Other observations

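All tests in this part were chosen after the data were seen, and for the test of cell cycle phase the values of a few of its genes, such as CDCA8 and ASF1B, had been seen as well. Beyond the fixed lists, families of at least 10 measured genes that share the letters of their symbols were compared, 125 in all, and 10 stood apart the same way in both GSK458 pairs. Host genes of small nucleolar RNAs (SNHG symbols, 18 genes) had medians of 0.72 without As2O3 and 0.25 with it, and the other RPL symbols of ribosomal proteins (30 genes, some of them pseudogenes) 0.51 and 0.17. Cytochrome P450 genes (14 genes) had medians of 0.55 and 0.48, and ZDHHC palmitoyltransferases (21 genes) 0.21 and 0.39. Lower were nuclear pore genes (NUP symbols, 21 genes, −0.43 and −0.49), proteasome regulatory subunits (PSMD symbols, 15 genes, −0.46 and −0.39), mitochondrial ribosomal proteins (MRPL symbols, 49 genes, −0.37 and −0.25), LSM proteins of RNA processing (13 genes, −0.41 and −0.63) and further NDUFA subunits (10 genes, −0.42 and −0.49). Each of these kept its direction under the 3 other scalings, whereas the zinc finger family (ZNF symbols, 404 genes, 0.09 and 0.16) kept it under 2 of the 3. The MRPS symbols of mitochondrial ribosomal proteins (30 genes, −0.28 and −0.22) and the other RPS symbols (18 genes, 0.31 and 0.10) stood apart only without As2O3. For As2O3, 4 families stood apart the same way in both pairs. COL symbols outside the fixed lists (11 genes, 1 of them, COL4A3BP, no collagen) were lower at −0.36 and −0.40. COL1A1 and the extracellular matrix list were instead higher with As2O3 against the control. In the combination against GSK458 both were lower like the COL symbols, the list at −0.26 (percentile 0). GOLGA (0.36 and 0.16), MYO (0.27 and 0.14) and RAD symbols (0.31 and 0.15) were higher in both pairs.

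The nuclear long noncoding RNA NEAT1 stood at 28.6 FPKM in the control, 20.05 with As2O3, 87.3 with GSK458 and 130.2 with both, and MALAT1 at 8.24, 10.7, 21.0 and 24.5 FPKM. The tubulin gene TUBA1B stood at 535, 594, 82.9 and 138 FPKM, and TUBB4B at 305, 321, 89.8 and 117 FPKM, each lower with GSK458. These genes were named after their values were seen.

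A hypothesis from the mitotic and S phase lists is that As2O3 leaves a larger share of cells in G2 or mitosis, with and without GSK458. It predicts that other genes of these phases, outside the fixed lists, part the same way. Among 40 other G2 and mitosis genes and 35 other S phase genes, the difference of medians was 0.276 with As2O3 against the control (percentile 99.7 of matched random lists). It was 0.319 in the combination against GSK458 (percentile 100), and both values went the way the hypothesis predicts. The median of the other G2 and mitosis genes was 0.29 and 0.51 in these pairs, and that of the S phase genes 0.02 and 0.19, while both were well below 0 in GSK458 against the control, at −1.85 and −1.32. These genes were read in the same libraries as the fixed lists and belong to the same phases, so they would move with those lists under other causes too. Random lists of unrelated genes do not allow for this. The values therefore cannot tell a larger share of cells from a change in expression of these genes. In the combination against GSK458, a smaller GSK458 effect in that culture cannot be told apart either. With 1 library per group, a chance difference between cultures may give the same values, and no measurement of cell cycle phase was used here.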
